A study of Oryza sativa with 16 samples.

How the data were processed

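Transcript levels were measured with 16 Agilent rice 44K arrays hybridised with a single Cy3-labelled sample each, 4 per group: wild type (Nipponbare) and the line npr1-7, each with mock or BTH treatment. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, RNA was extracted from the fourth leaves, amplified linearly and labelled. The arrays were scanned and read with Agilent Feature Extraction 9.1, per the submitters' processing notes, and the file headers give version 9.1.3.1 and a single-colour gene expression protocol. The spot intensity used here is the processed signal, which per the file headers had been background-subtracted and corrected for spatial and multiplicative trends within each array by that software, with low values replaced by surrogates, and was not scaled between arrays. The authors also deposited a table of the series whose values were set against the scanner signals array by array. They are a linear ratio to each probe's median over the mock-treated wild-type arrays, deposited by the authors, with correlations across probes of 0.991 to 0.999 with the scanner values treated in that way. Of its 40841 probes 40838 were matched. Its column medians were 1.004, 0.993, 0.971 and 1.054 for BTH-treated wild type, 0.972, 0.987, 1.019 and 1.019 for mock-treated wild type, 1.07, 1.007, 1.033 and 0.965 for BTH-treated npr1-7, and 1.089, 0.948, 1.006 and 0.954 for mock-treated npr1-7. How its columns were scaled between arrays stays unknown. These ratios served as an alternative input.

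Each array held 45151 spots, of which 43734 were not controls and made up 42477 distinct probes. A gene locus was given in the files for 41908 probes, covering 29690 loci, and 510 probes were for microRNAs. Between 69.9 and 75.2% of the spots per array were well above background, and at most 1 spot per array was saturated. The main values are log2 of the processed signal minus each array's 75th percentile over the spots that are not controls. Control spots and outlier spots were left out and saturated spots were kept. Spots of the same probe were averaged. A gene was represented by its probe with the highest mean signal over all arrays, and a feature was tested if its probe was well above background on all 4 arrays of at least 1 group. A further 84 features were removed because outlier spots left a group without a value. Of the named genes in the text, such spots left 2 arrays in BTH-treated wild type for Os03g0300400, 3 in that group for Os01g0501800 and in both wild-type groups for Os12g0555500, and 3 in mock-treated wild type for Os03g0343900. This left 21127 of 30200 features (21047 loci and 80 microRNA probes). Gene names and loci are those of the array files, although the plan was to join probes through the reference table. The reference table, of assembly ASM3414082v1, held 39387 genes, and 0 loci and 0 accessions of the files matched it, so no name or coordinate was taken from it. Among 6300 genes with several tested probes, probes were called in opposite directions for 31 genes in wild type, 0 in npr1-7, 0 in the interaction, 4 under mock and 4 after BTH.

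All 16 arrays entered a single limma fit (lmFit and eBayes, limma 3.58.1 in R 4.3.3) with a mean per group and no covariates. Contrasts were BTH minus mock in each genotype, their difference (the interaction), and npr1-7 minus wild type in each treatment. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all features, two-sided. A dependent gene was called and changed at least 2-fold in wild type with a called interaction of opposite sign. The share kept is the npr1-7 log2 change divided by the wild-type change. Where a gene was not well above background on every array of the dimmer group, its fold is given as a lower bound, a rule planned for groups without such an array and widened after the values had been seen: the brighter group's mean was set against the mean of, per array, the higher of the lowest signal well above background and the gene's own. That lowest signal is over all probes of the array. The bound therefore holds under this rule only, and not for the detection limit of the gene's own spot. Both target genes were also tested with exact permutation, where 4 against 4 arrays give a smallest p of 0.0286. Data were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and the R package data.table (1.17.8), and drawn with matplotlib 3.10.9.

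The design, the alternatives, the rule for named genes and 28 gene lists were fixed before the data were examined. The rule names both target genes and curated defence genes whatever their values, the 8 largest changes of each sign for BTH in wild type and for the interaction and the 5 largest for the other contrasts, and up to 4 members of each list and contrast with the smallest p in the direction of the list. The largest changes were taken among called genes whose product is named, that were well above background on all arrays of the brighter group and whose array values did not overlap between the groups (for the interaction, among the dependent genes). Lists were made from product names and loci, and cover SA receptors, WRKY factors, pathogenesis-related proteins, diterpenoid phytoalexins, glutathione S-transferases, UDP-glycosyltransferases, P450s, class III peroxidases, phenylpropanoids, shikimate and aromatic amino acids, jasmonate, ethylene, receptor kinases, NB-LRR proteins, ER folding, heat shock proteins, photosystems, the Calvin cycle, plastid ribosomes, tetrapyrroles, senescence, cytosolic ribosomes, the proteasome, and markers of dividing and expanding cells, vascular tissue, seed and pollen, and dehydration. Product names that matched 13 of the lists by accident were taken out after names, but no test results, had been seen. Names that mark a product without a database hit were barred from naming after values had been seen. Which of the genes that the rule names are printed was decided with their values in view. Lists were tested with camera, with a preset correlation of 0.01 and with an estimated correlation, adjusted over the lists within a contrast.

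The fit and the list test were tested on simulated data drawn with the mean and spread of the 21127 features. Changes were put into 1 group for features drawn at random. The noise was normal and independent between features and arrays, with 1 spread per feature for all groups. Deviations shared by the genes of an array were thus not simulated. For BTH in wild type 21.7, 71.2 and 98.5% of genes with a true log2 change of 0.5, 1 and 2 were recovered, and for the interaction 17.9, 71 and 89.3%, with 9 unchanged genes called in each. Alternatives were quantile normalization, the median as scale, normexp background correction (offset 50) of the mean spot signal with the local background, no detection filter or a filter on all 16 arrays, the replicate number as a block, fits of the compared groups alone, a trended robust prior, array weights, probes kept apart or averaged, a 2-fold threshold, other fold thresholds for dependent genes, shares with genes chosen on replicates 1 and 2 of wild type and measured on 3 and 4, the deposited ratios, and leaving out each array. Leaving out together 2 arrays that stood apart from their groups, and lists with the accidental names put back, were added after seeing the data. Slide and scan could not be blocked, because each group lay on a slide and scan of its own.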

Results

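Transcript levels were measured in rice (Oryza sativa) leaves on 16 single-colour arrays, 4 in each of 4 groups. The wild type was the cultivar Nipponbare, and the other genotype was a transgenic knockdown line called npr1-7 in the sample titles. Shoots cut from seedlings stood for 24 h in 10 µM benzothiadiazole (BTH), a synthetic compound that switches on the salicylic acid (SA) branch of plant defence, or in 0.01% DMSO as the mock treatment, and RNA came from the fourth leaf. The design text calls the 4 samples of a group biological replicates, and their number limits the precision of every value. On single arrays 69.9 to 75.2% of the gene spots were well above background. Log2 values of arrays of the same group correlated across genes, which are not independent replicates, with r from 0.958 to 0.991, and those of different groups with r from 0.892 to 0.979. Replicate 1 of mock-treated npr1-7 correlated with its own group at r from 0.958 to 0.9752. With the mock-treated wild-type arrays its r was no lower, from 0.9715 to 0.9768. Replicate 3 of BTH-treated wild type correlated with its own group at r from 0.9711 to 0.9792. With the BTH-treated npr1-7 arrays its r was nearly as high, from 0.9683 to 0.9787. The 4 arrays of each group lay on a slide of their own, so slide and group cannot be told apart in any comparison. The design text names 2 knockdown lines, of which 1 was analysed here. Log2 values are relative to each array's 75th percentile. Changes are given on the log2 scale with the standard error (SE) of the limma fit over all 16 arrays, and their p values are two-sided.

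The knockdown target was examined in every array before anything else, because the title and line name point to NPR1 while the line label calls the plants a WRKY45 knockdown. NPR1 (Os01g0194300, listed as NPR1-like protein) is the rice counterpart of the central SA co-regulator of Arabidopsis, and WRKY45 (Os05g0322900) encodes a transcription factor of the same pathway. In mock-treated wild type NPR1 read -1.46, -1.03, -1.32 and -1.52, a mean of -1.33 ± 0.22 (SD, n = 4). In mock-treated npr1-7 it read -2.32, -1.84, -1.47 and -1.11, a mean of -1.69 ± 0.52 (SD, n = 4). The mock difference of -0.36 (SE 0.25), equal to 78.1% of the wild-type level, was within the spread (adjusted p = 0.423, exact permutation p = 0.257). With BTH, wild type read 0.32, -0.31, -0.77 and -0.17, a mean of -0.23 ± 0.45 (SD, n = 4), and npr1-7 read -2.04, -2.17, -2.35 and -1.81, a mean of -2.09 ± 0.23 (SD, n = 4). NPR1 thus stood at 27.5% of the wild-type level after BTH, a difference of -1.86, SE 0.25 (adjusted p = 0.000687), with no overlap of the arrays. The exact permutation p of 0.0286, two-sided, is the smallest that 4 against 4 arrays can give. BTH raised NPR1 by 1.10 (SE 0.25) in wild type (adjusted p = 0.00295), whereas its change in npr1-7 was -0.41 (SE 0.25, adjusted p = 0.305). The difference between these responses, -1.5 (SE 0.35), missed the threshold (adjusted p = 0.0953), and passed it without replicate 3 of BTH-treated wild type, at -1.68 (adjusted p = 0.0190). With array weights both the change in npr1-7 (adjusted p = 0.0145) and the difference between the responses (adjusted p = 0.00393) passed by limma. The weights of replicates 1 to 4 were 0.29, 1.38, 3.68 and 0.64 in mock-treated npr1-7 and 0.91, 3.1, 1.03 and 0.69 in BTH-treated npr1-7. Replicate 1 of mock-treated npr1-7, with the lowest NPR1 of its group, thus counted least there. A second NPR1 probe gave -0.10 under mock (adjusted p = 0.848) and -1.64 after BTH (adjusted p = 0.00123).

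WRKY45 rose strongly with BTH in both genotypes. In wild type it read -0.64, -1.61, -0.10 and -1.83 under mock and 4.26, 4.00, 3.69 and 4.23 after BTH, a change of 5.09 (SE 0.60) or 34.1-fold (adjusted p = 5.22e-05). In npr1-7 it read -3.85, -1.5, -1.34 and 0.03 under mock and 4.39, 4.23, 3.87 and 4.18 after BTH, a change of 5.83 (SE 0.60) or 56.9-fold (adjusted p = 3.26e-05). Between the genotypes it differed by -0.62 (SE 0.60, adjusted p = 0.574) under mock and by 0.12 (SE 0.60, adjusted p = 0.906) after BTH, and neither difference passed the test. Without replicate 1 of mock-treated npr1-7 the change in npr1-7 was 5.10 and the mock difference 0.11, and without its replicate 4 they were 6.40 and -1.19, so the sign of the latter depends on a single array. Exact permutation p values were 0.629 and 0.571, and none of the 4 WRKY45 probes passed the limma test between genotypes in either treatment. All probes of both genes read coding sequence and 3′ untranslated region. Whether they also read transcript of the silencing construct is not known from the sources used here.

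**Figure D1:**
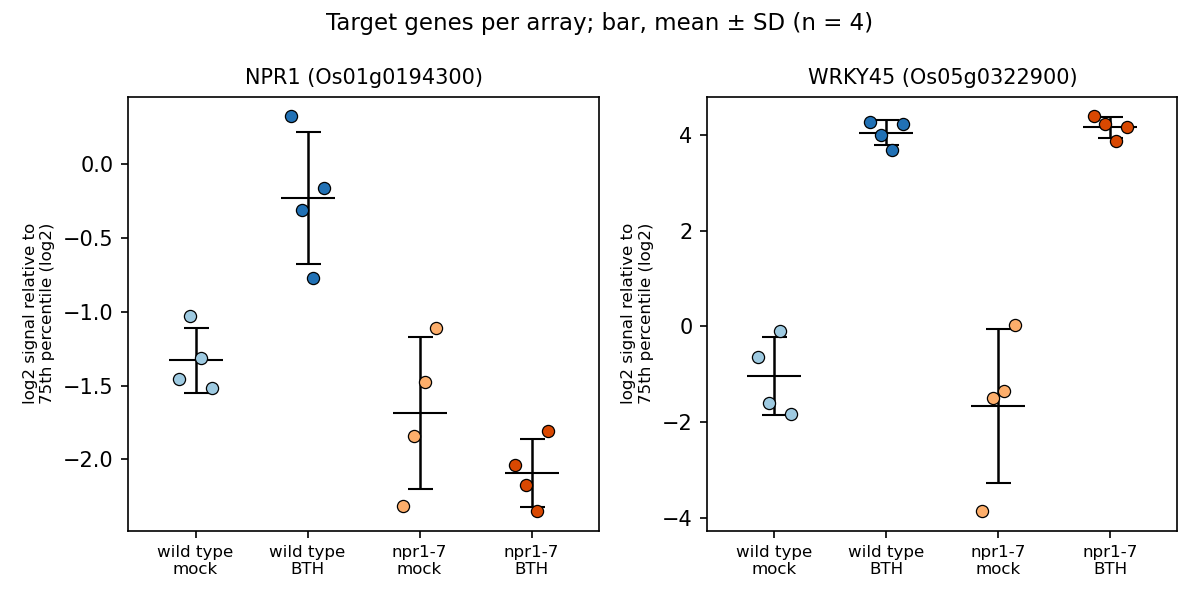
Log2 signal of NPR1 and WRKY45 relative to each array's 75th percentile (vertical axes, log2) in the 4 groups, with a point per array and a bar for the mean ± SD (n = 4). NPR1 after BTH averaged -0.23 in wild type and -2.09 in npr1-7 with no overlap, while WRKY45 after BTH averaged 4.05 and 4.17.

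The first comparison asked which genes respond to BTH in wild type. Lipoxygenase L-2 (Os03g0738600), of an enzyme class that oxidises fatty acids on the way to jasmonate and other oxylipins, rose at least 496-fold. A group I P450 gene (Os10g0515900) rose at least 496-fold and a beta-glucosidase aggregating factor gene (Os12g0247700) 504-fold (8.98, SE 0.67). The transcription factor genes WRKY64 (Os12g0116700) and WRKY50 (Os11g0117600) rose at least 234-fold and at least 252-fold, and a further WRKY domain gene (Os09g0417800) at least 204-fold. A SAM-dependent carboxyl methyltransferase gene (Os02g0719600) and a transferase family gene (Os12g0458100) rose at least 289-fold and at least 285-fold. Where a gene was not well above background on every array of the dimmer group, the fold is such a lower bound. It is set against the lowest signal well above background of any probe, or the gene's own signal where higher. The detection limit of the gene's own spot is not known, so the true fold could be smaller. Mock arrays well above background numbered 1 of 4 for Os03g0738600 and Os10g0515900, 2 for Os09g0417800 and 0 for the other 4 genes with a bound. Among 21127 genes and other features tested, 10405 changed (49.2%), 5097 upward and 5308 downward, and 2929 of them by at least 2-fold (1368 up, 1561 down).

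The genes that fell most after BTH included an O-methyltransferase gene (Os09g0344500, at least 117-fold lower), a nonspecific lipid transfer protein gene (Os05g0550600, at least 97.8-fold) and a terpene synthase-like gene (Os04g0344100, at least 88.6-fold). A jacalin-related lectin gene (Os01g0348900) fell by 5.90 (SE 1.47), an NADP-dependent malic enzyme gene (Os01g0743500) fell at least 34.6-fold and a type 1 metallothionein-like gene (Os12g0568200) at least 27.7-fold. A haem peroxidase gene (Os06g0695400) fell at least 22.1-fold, and a dehydrin gene (Os11g0454300), of a family linked to water deficit, fell by 5.40 (SE 1.44). Of the 4 BTH arrays 2, 3, 3, 2, 1 and 0 were well above background for the 6 genes with a bound, in the order named. Adjusted p values of these 8 genes lay between 0.000224 and 0.00785. In the mock comparison, which shares the wild-type mock arrays, the same 8 genes read between -3.23 and -6.39 in npr1-7 relative to wild type (adjusted p from 0.00659 to 0.210).

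Defence gene families rose with BTH in wild type. Of 59 WRKY genes tested 31 rose and 6 fell (33 and 7 adjusted over the list alone), and their median change was 0.80. Among 83 pathogenesis-related protein genes 30 rose and 11 fell (33 and 12 adjusted over the list alone), including Bowman-Birk proteinase inhibitor genes Os01g0127600 (at least 42.3-fold) and Os01g0123900 (2.08, SE 0.18). The defence marker PR1a (Os07g0129200) rose at least 20.5-fold (3 of 4 mock arrays well above background, as for Os01g0127600), and the probenazole-inducible PBZ1 genes Os12g0555500 and Os12g0555300 rose by 2.62 (SE 0.45) and 2.45 (SE 0.61). All 3 tested SA receptor and partner genes rose (3 adjusted over the list alone), namely NPR1, a second NPR1-like gene (Os01g0767900, 0.86, SE 0.13) and a BTB/POZ gene (Os03g0667100, 2.07, SE 0.22). The jasmonate list rose in 12 of 19 genes and fell in 4 (12 and 4 adjusted over the list alone), with lipoxygenase genes Os12g0560200 (6.68, SE 0.40) and Os12g0559200 (6.61, SE 0.40). The camera test placed the WRKY, pathogenesis-related, SA and jasmonate lists above the other genes with the preset correlation (adjusted p = 2.24e-05, 0.00604, 0.00755 and 0.00168). With an estimated correlation none passed, at adjusted p = 0.278, 0.368, 0.278 and 0.278. Under normexp background correction the WRKY and pathogenesis-related medians were 0.13 and 0.014, from 0.80 and 0.41, while that of all genes was -0.31, and both lists passed the test. A PR10-type gene (Os03g0300400) read 0.92, SE 0.31 on 2 BTH arrays, the others being left out as outlier spots. Its call (adjusted p = 0.0286) leans on the spread of the other groups and ended without either of these BTH arrays, which leaves a single one (adjusted p = 0.113 and 0.0784), and without replicate 2 or 4 of mock-treated wild type (adjusted p = 0.0555 and 0.0673).

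Genes of secondary metabolism and detoxification also rose. Of 44 glutathione S-transferase genes 27 rose and 5 fell, with Os01g0949700 at 3.64, SE 0.21. Of 103 UDP-glycosyltransferase genes 45 rose and 18 fell, with Os09g0518200 at 7.19, SE 0.33. In the phenylpropanoid and lignin list 20 of 29 genes rose and 0 fell, among them phenylalanine ammonia-lyase genes Os04g0518400 (at least 40.6-fold, 3 of 4 mock arrays well above background) and Os02g0627100 (3.66, SE 0.54), which encode the entry step of that pathway. In the shikimate and aromatic amino acid list 17 of 29 rose and 4 fell, with the indole-3-glycerol phosphate lyase gene Os03g0797500 at least 105-fold higher. Adjusted over the list alone the counts up and down were 29 and 6, 50 and 19, 21 and 0, and 17 and 4. Preset camera tests gave adjusted p = 7.59e-05, 0.00136, 3.45e-06 and 0.00254 for these 4 lists, and with an estimated correlation adjusted p = 0.278, 0.278, 0.278 and 0.331. Under normexp background correction the glutathione S-transferase median went from 0.73 to 0.29 and that of UDP-glycosyltransferases turned from 0.37 to -0.12, both past the test (adjusted p = 1.00e-05 and 0.0223). The diterpenoid phytoalexin list rose in 5 of 6 genes (6 adjusted over the list alone; adjusted p = 0.0203, and 0.360 with an estimated correlation), with copalyl diphosphate synthetase (Os04g0178300) at 2.21, SE 0.64. Under normexp background correction the list median turned from 2.1 to -0.26 (adjusted p = 0.740) and that gene read 0.40 (adjusted p = 0.505), and the list call also ended without replicate 3 of BTH-treated wild type (adjusted p = 0.0536). Cytochrome P450 genes went both ways, with 50 of 149 up and 40 down and no shift of the list past the threshold (adjusted p = 0.573), and so did class III peroxidase genes, with 7 of 24 up and 5 down (adjusted p = 0.704).

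Protein synthesis and turnover genes rose by small amounts. Of 143 cytosolic ribosomal protein genes 135 rose and 0 fell, with a median of 0.70 (1.62-fold), for example L30 (Os01g0812800, 1.31, SE 0.19) and L40 (Os09g0568400, 0.98, SE 0.14). In the list of endoplasmic reticulum (ER) folding and secretion genes 38 of 56 rose and 2 fell, among them a SEC61 beta subunit gene (Os01g0565900, 0.78, SE 0.14) and calreticulin (Os07g0246200, 0.44, SE 0.08). Of 39 proteasome genes 20 rose and 1 fell, for example beta type 1 (Os08g0529100, 1.76, SE 0.21). Counts adjusted over the list alone were the same for these 3 lists. The preset test gave adjusted p = 3.91e-25, 1.68e-06 and 1.35e-05, and the estimated correlation adjusted p = 0.331, 0.278 and 0.329.

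Photosynthesis and plastid genes fell in wild type. These lists were chosen with the theme of the study in mind and so are not independent evidence of their direction. Of 40 photosystem and light-harvesting genes 27 fell and 0 rose, with a median of -1.32 (2.50-fold lower), including a chlorophyll a/b-binding protein gene (Os09g0439500, -2.92, SE 0.45) and oxygen-evolving enhancer protein 1 (Os01g0501800, -2.0, SE 0.30). Among 46 plastid ribosome genes 27 fell and 11 rose, with plastid 50S protein L9 (Os02g0822600) at -2.11, SE 0.26 and 30S protein S13 (Os03g0704000) at -1.83, SE 0.22. In the chlorophyll and tetrapyrrole list 9 of 16 fell and 2 rose, with protochlorophyllide reductase A (Os04g0678700), an enzyme of chlorophyll synthesis, at least 5.81-fold lower (1 of 4 BTH arrays well above background). Of 28 Calvin cycle and photorespiration genes 12 fell and 1 rose, with glycolate oxidase (Os03g0786100) at -0.86, SE 0.19. Adjusted over the list alone 28, 27, 10 and 12 genes fell. Preset camera tests gave adjusted p = 2.10e-07, 0.00143, 0.00755 and 0.0487, and with an estimated correlation adjusted p = 0.360, 0.477, 0.360 and 0.368. The estimated correlations of these lists were 0.533, 0.3, 0.251 and 0.086, against the preset 0.01. The calls of the last 3 lists ended under normexp background correction (adjusted p = 0.0917, 0.0841 and 0.341), with medians of -0.62, -0.53 and -0.65 there, against -0.31 for all genes, and of -0.76, -0.54 and -0.41 without it. With the accidental product names put back the photosystem median was -0.87. The Calvin cycle call also ended with the replicate number as a block (adjusted p = 0.0533) and in 7 of the 16 fits that left out an array, with the largest adjusted p, 0.103, without replicate 3 of BTH-treated wild type.

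The other lists did not pass the camera test in wild type. Of 148 NB-LRR resistance genes 34 rose and 29 fell (adjusted p = 0.851), of 63 receptor kinase genes 21 and 16 (adjusted p = 0.782), of 40 heat shock protein genes 13 and 11 (adjusted p = 0.851) and of 20 ethylene genes 5 and 7 (adjusted p = 0.851). Chlorophyll breakdown and senescence genes rose in 3 of 11 and fell in 2 (adjusted p = 0.880). In the ethylene and senescence lists the median, 0.06 and -0.02, and the test differed in sign. Markers of dividing cells rose in 7 of 40 and fell in 7 (adjusted p = 0.926), and those of cell expansion in 5 and 9 of 31 (adjusted p = 0.686). For dehydration and abscisic acid genes, fixed as a marker of shoot excision, the counts were 5 and 16 of 44 (adjusted p = 0.15), for vascular markers 0 and 1 of 9 (adjusted p = 0.529) and for seed and pollen markers 4 and 0 of 7 (adjusted p = 0.103). Under normexp background correction the NB-LRR list passed in the opposite direction, with a median of -0.77 (adjusted p = 0.0221). The dehydration list passed under quantile normalization (adjusted p = 0.0499) and without replicate 2 of mock-treated wild type (adjusted p = 0.0414).

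**Figure D2:**
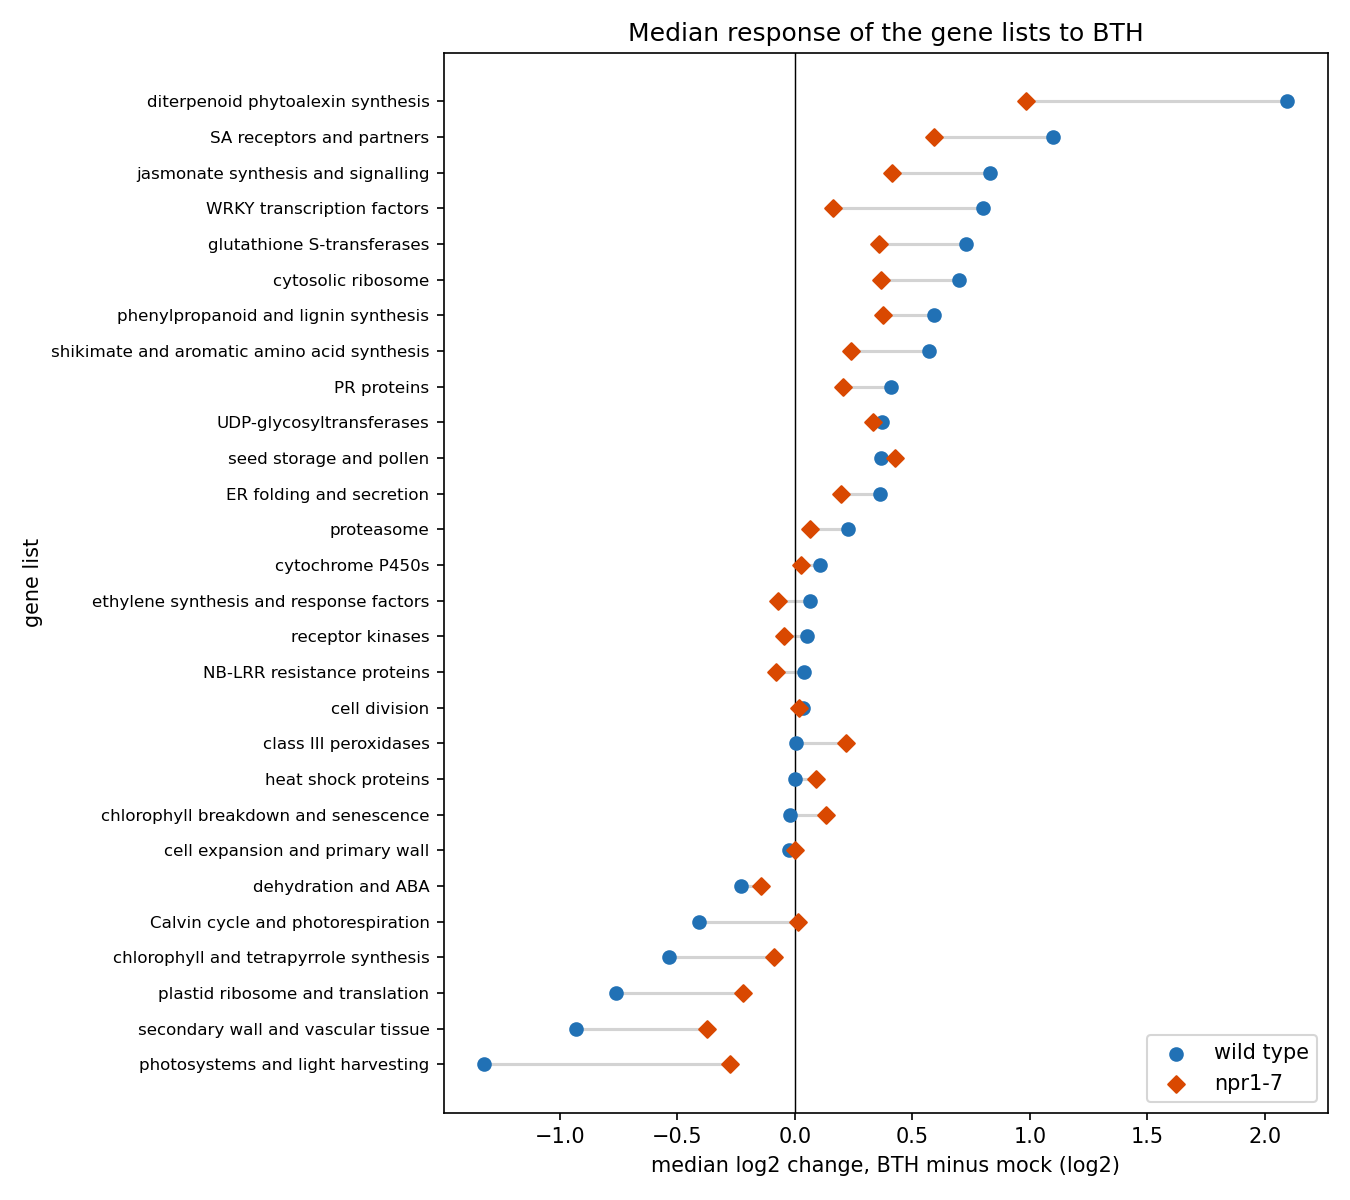
Median log2 change after BTH (horizontal axis, log2) of the 28 gene lists in wild type and in npr1-7, with a marker for each genotype. The photosystem list had medians of -1.32 and -0.28 and the cytosolic ribosome list 0.70 and 0.37.

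The second comparison asked which genes respond to BTH in npr1-7. Lipoxygenase L-2 (Os03g0738600) rose at least 536-fold, the transferase family gene Os12g0458100 at least 438-fold, the beta-glucosidase aggregating factor gene Os12g0247700 474-fold (8.89, SE 0.67), a bHLH gene (Os01g0108400) at least 176-fold and the WRKY domain gene Os09g0417800 at least 178-fold. The strongest falls among genes named by the fixed rule were those of a protein kinase gene (Os02g0154200, -2.40, SE 0.11), a barwin gene (Os11g0592100, at least 4.39-fold, 1 of 4 BTH arrays well above background) and a P450 gene (Os02g0184700, -1.83, SE 0.29). A resistance protein candidate (Os07g0575600) fell by 1.60 (SE 0.31) and a dienelactone hydrolase gene (Os05g0429500) by 1.59 (SE 0.32). The calls of Os11g0592100 and Os07g0575600 ended under normexp background correction (adjusted p = 0.197 and 0.10). In total 1559 genes changed (890 up, 669 down), 554 of them at least 2-fold (495 up, 59 down). The total was 2354, 628 and 765 without replicate 1, 2 or 3 of mock-treated npr1-7, 766, 869 and 947 without replicate 1, 2 or 4 of BTH-treated npr1-7, 407 under normexp background correction, 7039 with array weights and 2974 without replicate 3 of BTH-treated wild type and replicate 1 of mock-treated npr1-7 together, a choice made after seeing the data.

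Defence and metabolic lists also rose in npr1-7. WRKY genes rose in 13 of 59 (18 adjusted over the list alone), pathogenesis-related genes in 12 of 83 (15), glutathione S-transferases in 15 of 44 (20), UDP-glycosyltransferases in 21 of 103 (29), phenylpropanoid genes in 8 of 29 (12) and jasmonate genes in 6 of 19 (8). In the same order 0, 2, 1, 4, 0 and 1 of them fell (1, 5, 3, 8, 0 and 1 adjusted over the list alone). Examples were phenylalanine ammonia-lyase Os04g0518400 (6.30, SE 0.62), lipoxygenase Os12g0560200 (6.50, SE 0.40) and glutathione S-transferase Os01g0949700 (3.04, SE 0.21). Preset camera tests gave adjusted p = 6.81e-06, 0.00161, 3.77e-08, 3.77e-08, 6.81e-09 and 3.77e-08 for these 6 lists, and the estimated correlation adjusted p = 0.226, 0.357, 0.0622, 0.0622, 0.126 and 0.0622. The shikimate, ER, cytosolic ribosome, proteasome, SA receptor and diterpenoid lists passed the preset test as well, with 4 of 29, 7 of 56, 6 of 143, 2 of 39, 2 of 3 and 1 of 6 members called upward. Adjusted over the list alone 9, 13, 84, 2, 2 and 2 of them rose, and 1, 1, 1, 0, 0 and 0 fell (1, 0, 0, 0, 0 and 0 over all genes). Their preset adjusted p values were 0.000121, 1.85e-06, 3.40e-26, 0.0228, 0.0238 and 0.0189, and with an estimated correlation the adjusted p values were 0.226, 0.226, 0.336, 0.547, 0.280 and 0.357. The SA receptor call ended without replicate 1 of mock-treated npr1-7 (adjusted p = 0.0673), the diterpenoid call without the same array or under normexp background correction (adjusted p = 0.0729 and 0.115), and the proteasome call under quantile normalization (adjusted p = 0.154) and without replicate 1 of BTH-treated or replicates 2 or 4 of mock-treated npr1-7 (adjusted p = 0.0513, 0.0590 and 0.0637). None of the 40 photosystem genes was called in npr1-7 by limma (2 lower and 0 higher at an unadjusted p under 0.05), where the list median was -0.28 (adjusted p = 0.124). That list passed the test without replicate 1 of mock-treated npr1-7, with a median of -0.47 (adjusted p = 0.00122), without replicate 2 of BTH-treated npr1-7 (adjusted p = 0.0456) and under normexp background correction (adjusted p = 0.0398). Of the other lists that missed the test, P450 and heat shock genes passed in 3 of 20 alternative fits each, and NB-LRR, class III peroxidase and seed and pollen genes in 1 each.

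The third comparison asked which responses to BTH depend on the line, by the interaction of genotype and treatment. A thylakoid lumenal 15 kDa protein gene (Os01g0144100) read -2.90 in wild type and -0.58 in npr1-7, an interaction of 2.32, SE 0.39 (adjusted p = 0.0454). GTP cyclohydrolase II (Os05g0460600), of riboflavin synthesis, read -1.92 against -0.18 (interaction 1.74, SE 0.29), and a PfkB carbohydrate kinase gene (Os01g0851000) -2.02 against -0.52 (1.5, SE 0.22). The P450 71A1 gene Os06g0642500 had a fitted interaction of 2.63, SE 0.44, but was not well above background on any BTH array of either line, which leaves the size of its responses unknown. The P450 genes Os10g0513400 and Os10g0514500 rose by 4.55 and 2.99 in wild type and by 2.03 and 1.12 in npr1-7 (interactions -2.52, SE 0.34, and -1.87, SE 0.26). In all 16 features passed (12 with a positive and 4 with a negative interaction), against 3806 at an unadjusted p under 0.05. With the replicate number as a block limma called 0 features (3574 at an unadjusted p under 0.05) and 0 dependent genes, and the 6 genes named here read adjusted p = 0.0530 to 0.123. Fits without an array ended the call of Os01g0144100 in 13 of 16 (adjusted p up to 0.139), of Os05g0460600 in 12 (up to 0.119), of Os06g0642500 in 10 (up to 0.110), of Os01g0851000 in 6 (up to 0.0683) and of Os10g0513400 and Os10g0514500 in 4 each (up to 0.0683 and 0.0727), and quantile normalization ended that of Os01g0144100 (adjusted p = 0.0532). Of the 2929 wild-type responsive genes 15 had a significantly smaller response in npr1-7 (3 induced, 12 repressed) and 0 a larger one by limma. This count includes fitted responses that turned, such as Os10g0112800 (-2.93 in wild type, 0.88 in npr1-7), Os02g0332800 (-1.47, 0.83) and Os04g0106500 (2.21, -1.04). Of the repressed genes 1 was called upward in npr1-7. By limma 0 genes passed without replicate 2 of BTH-treated npr1-7 or without replicate 2 or 3 of mock-treated npr1-7 (3099, 3566 and 3233 at an unadjusted p under 0.05). The total was 8, 4 and 6 without replicate 1, 2 or 4 of BTH-treated wild type, 36 and 39 without replicate 2 or 4 of mock-treated wild type, 5 and 1 without replicate 1 or 3 of BTH-treated npr1-7, 8 without replicate 4 of mock-treated npr1-7 and 4008 with array weights. In contrast 1251 passed without replicate 3 of BTH-treated wild type, 107 without replicate 4 of BTH-treated npr1-7 and 2357 without replicate 3 of BTH-treated wild type and replicate 1 of mock-treated npr1-7 together. Dependent genes numbered 103 under normexp background correction, 1594 with array weights and 1298 without the 2 arrays together. The interactions of the 3 named P450 genes also missed the threshold under normexp background correction (adjusted p = 0.168, 0.181 and 0.250), which called 111 features in all. In simulated data the interaction test recovered 71% of genes with a true interaction of 1 and 89.3% of those with 2. Those data had independent noise and no deviation shared by the genes of an array, so such rates may be too high for the real arrays. Their changed genes were drawn at random from all features, not from the genes responsive to BTH. Of the 1561 repressed genes, whose median fitted interaction was 1.04 on the arrays that chose them, 12 were called.

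Across all wild-type responsive genes the median share of the response kept in npr1-7 was smaller for repressed than for induced genes, in each of the 4 BTH-treated npr1-7 arrays. The 1368 induced genes kept a median share of 0.596 of the wild-type log2 change (quartiles 0.399 and 0.821), and the 1561 repressed genes a median of 0.305 (quartiles 0.193 and 0.423). Single BTH-treated npr1-7 arrays gave 0.471 to 0.670 and 0.146 to 0.419 (SD 0.093 and 0.126, n = 4). All 4 arrays were set against the same npr1-7 mock mean and the same wild-type change. The SD therefore leaves out the spread of the other groups, and the 4 shares are not independent repeats of the difference. In npr1-7 557 of the induced and 114 of the repressed genes passed the test in the same direction. WRKY45, well above background on all 16 arrays, had a share of 1.15. Choosing genes for a large change in wild type can overstate that change. When they were chosen on replicates 1 and 2 of wild type and measured on 3 and 4, as planned, the shares were 0.720 and 0.434. Over all 6 choices of such a pair they ranged from 0.654 to 0.761 and from 0.251 to 0.448, and were higher in each of the 3 choices that measured on replicate 3, so selection and replicate 3 are not told apart by the planned choice. The share of the repressed genes was 0.156 under normexp background correction, and that of the induced genes 0.497 without replicate 3 of BTH-treated wild type and 0.433 without the 2 arrays together.

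In the interaction 7 of the 28 gene lists passed the preset camera test, and 0 passed with an estimated correlation. Of 100 splits of the same arrays, the real one among them, 44 gave at least as many passing lists. Chance thus cannot be excluded for that number. Photosystem and light-harvesting genes had a median interaction of 1.04, that is, a smaller fall in npr1-7, with 0 of 40 genes past the threshold over all genes and 19 adjusted over the list alone. The plastid ribosome list had a median of 0.59 (0 of 46, and 21 up and 2 down adjusted over the list alone), the tetrapyrrole list 0.37 (0 of 16, and 7 up and 1 down) and the Calvin cycle list 0.46 (0 of 28, and 1 up). Preset camera tests gave adjusted p = 5.08e-11, 1.28e-05, 0.000311 and 0.000754, and the estimated correlation adjusted p = 0.583, 0.685, 0.583 and 0.583. Single members included PsbX (Os03g0343900, 2.48, SE 0.59, adjusted p = 0.0957) and oxygen-evolving enhancer protein 1 (Os01g0501800, 1.71, SE 0.41, adjusted p = 0.0957), which missed the threshold. The cytosolic ribosome, proteasome and ER lists had negative medians of -0.31, -0.17 and -0.15 with no member past the threshold over all genes and 0, 3 and 0 adjusted over the list alone. Their preset adjusted p values were 1.87e-11, 1.04e-05 and 0.00317, and with an estimated correlation the adjusted p was 0.685, 0.583 and 0.685. WRKY genes, with a median of -0.26 (adjusted p = 0.0845), and pathogenesis-related genes, with -0.24 (adjusted p = 0.278), did not pass this test. Under normexp background correction both medians turned, to 0.32 and 0.14, while that of all genes was 0.24. The WRKY list passed without replicate 1 of mock-treated npr1-7 (adjusted p = 0.000615), replicate 2 of BTH-treated wild type (adjusted p = 0.0172) or replicate 1 or 4 of mock-treated wild type (adjusted p = 0.0433 and 0.0265). Other lists that missed this test also passed in some of 20 alternative fits: dehydration genes (median 0.11, adjusted p = 0.138) in 5, vascular markers (0.60, adjusted p = 0.141) and phenylpropanoid genes (-0.19, adjusted p = 0.0976) in 4 each, expansion markers (0.22, adjusted p = 0.139) in 3, NB-LRR genes in 2, in opposite directions, and SA receptor, shikimate and receptor kinase genes in 1 each. Smallest adjusted p values of the first 4 were 0.0158, 0.0295, 0.000579 and 0.0425. Normexp background correction ended the Calvin cycle and plastid ribosome calls (adjusted p = 0.141 and 0.0887), with medians of 0.58 and 0.58 against 0.24 for all genes, and quantile normalization the ER call (adjusted p = 0.0581). Scaling to the median moved the proteasome and ER medians to -0.27 and -0.25. Without replicate 1 of mock-treated npr1-7 12 lists passed.

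**Figure D3:**
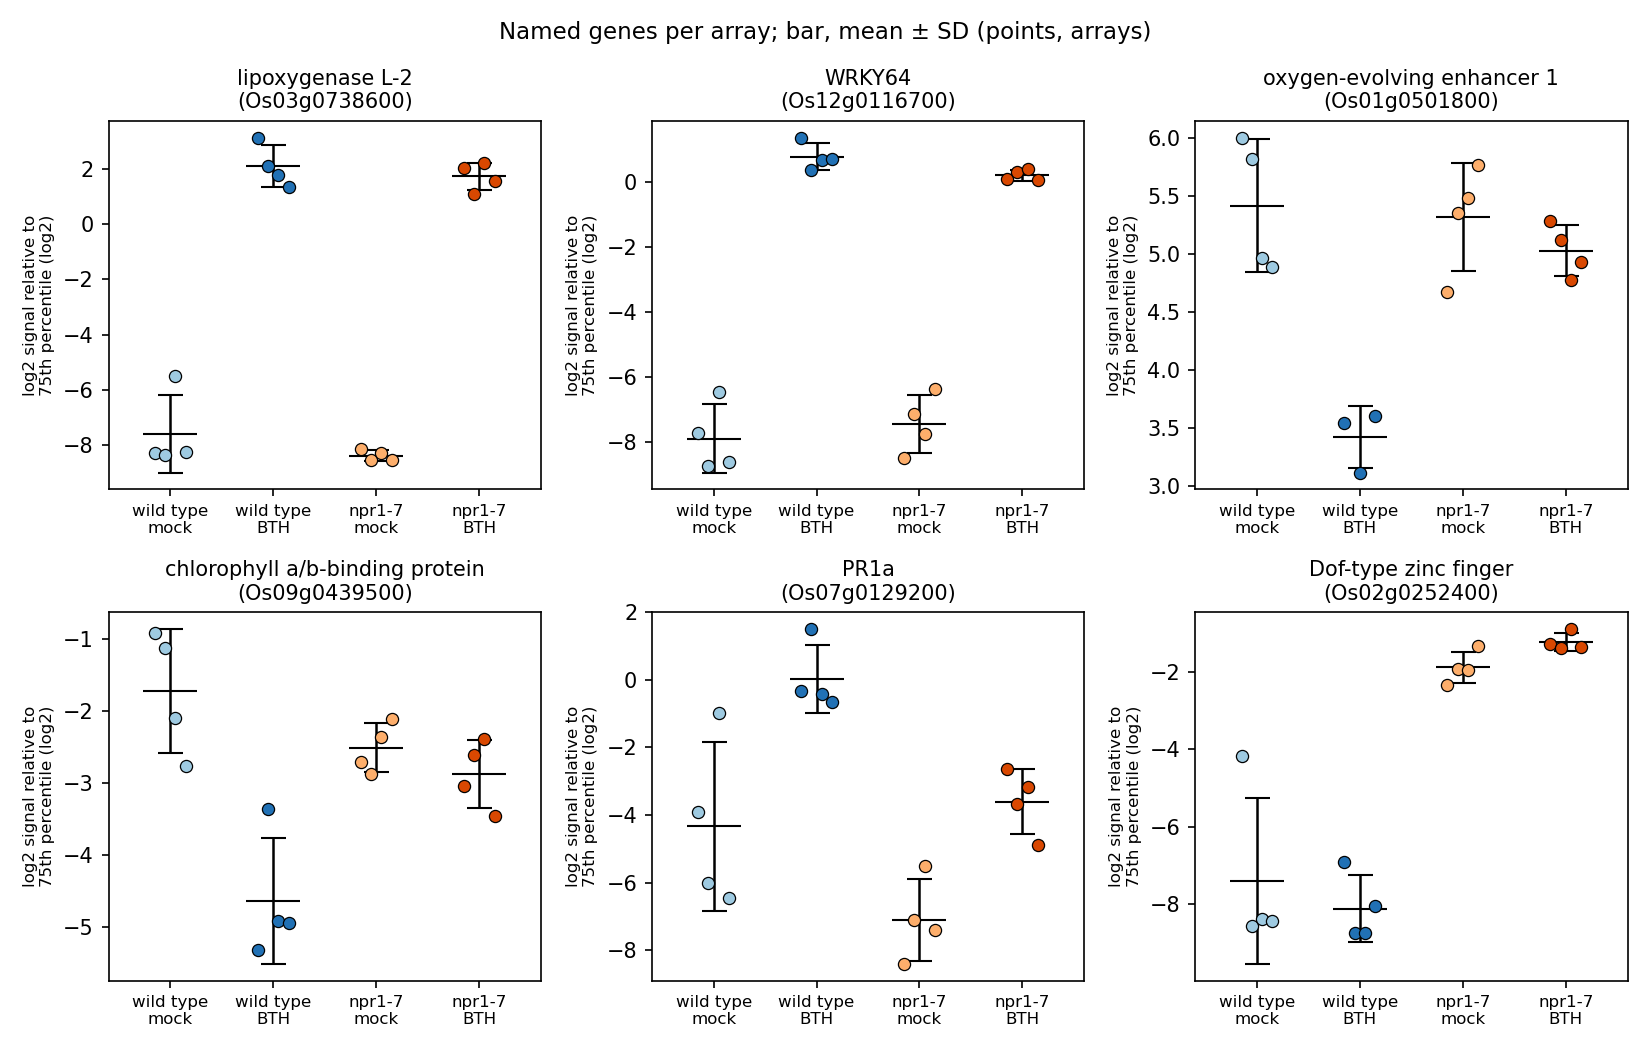
Log2 signal relative to each array's 75th percentile (vertical axes, log2) of 6 named genes in the 4 groups, with a point per array and a bar for the mean ± SD (n = 4, or 3 where an outlier spot was left out). Lipoxygenase L-2 (Os03g0738600) rose in both genotypes, whereas oxygen-evolving enhancer protein 1 (Os01g0501800) changed by -2.0 with BTH in wild type and by -0.29 in npr1-7.

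The fourth comparison asked how npr1-7 differed from wild type under mock treatment. A Dof-type zinc finger gene (Os02g0252400) stood at least 24.6-fold higher, a homeodomain-like gene (Os11g0282700) at least 18.4-fold and DRE-binding protein 1A (Os09g0522200), of a family of regulators of cold and drought genes, 20.5-fold (4.36, SE 0.91). An RNA helicase-like gene (Os06g0602400) stood at least 4.67-fold higher and a class 3 lipase gene (Os01g0309900) 6.06-fold. Lower in npr1-7 were an S10 carboxypeptidase gene (Os11g0461000, at least 11.1-fold), an AAA ATPase gene (Os01g0226400, at least 7.93-fold), a gibberellin-regulated gene (Os03g0607200, at least 9.26-fold), a P450 gene (Os10g0171500, at least 4.76-fold) and dehydrin RAB 16D (Os11g0453900, at least 8.32-fold). Of the 4 arrays of the dimmer group 1 each were well above background for Os02g0252400 and Os11g0282700, 0 for Os06g0602400 and 2, 1, 2, 2 and 0 for the 5 lower genes. In total 921 genes differed, 450 higher and 471 lower, and 301 of them at least 2-fold. The split was 326 higher and 2057 lower under normexp background correction, which moved the median of all genes by -0.24, and that correction ended the calls of Os02g0252400, Os11g0282700 and Os01g0309900 (adjusted p = 0.0654, 0.145 and 0.547) and turned Os06g0602400 to -0.68. The total was 3002, 387, 287 and 354 without replicate 1, 2, 3 or 4 of mock-treated npr1-7, 481 and 412 without replicate 1 or 3 of mock-treated wild type, 154 in a fit of the mock arrays alone, 4241 with array weights and 3382 without the 2 arrays together. Left-out arrays ended the calls of Os01g0226400 (6 of 16 fits, adjusted p up to 0.0890), Os10g0171500 (5 of 16, up to 0.0908), Os11g0461000 (2 of 16, up to 0.0683) and Os09g0522200 (1 of 16, 0.0565), with each of these largest values reached without replicate 3 of mock-treated npr1-7, and the replicate number as a block ended that of Os01g0226400 (adjusted p = 0.0505).

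Of the 28 lists 2 passed the preset test under mock, both lower in npr1-7. Heat shock protein genes had a median of -0.31 (5 of 40 lower and 1 higher, 13 and 1 adjusted over the list alone), with an Hsp20 gene (Os03g0266300) at -1.34, SE 0.22 and a further heat shock protein gene (Os01g0136200) at -1.12, SE 0.20. The dehydration and abscisic acid list had a median of -0.34 (2 of 44 lower and 0 higher, 7 and 1 adjusted over the list alone). Preset adjusted p values were 0.000135 and 0.00285, with an estimated correlation the adjusted p was 0.535 and 0.701, and both calls ended under normexp background correction (adjusted p = 0.0532 and 0.511), although the medians were larger there, -0.41 and -0.60, against -0.24 for all genes. With the accidental product names put back the heat shock median was -0.12. The expansion marker list had 4 of 31 genes lower (5 adjusted over the list alone), among them expansins Os02g0744200 (at least 4.01-fold) and Os01g0823100 (at least 10.7-fold), and no shift as a list (adjusted p = 0.191), although it passed under normexp background correction (adjusted p = 0.0430). Of the 4 npr1-7 arrays 0 and 1 were well above background for these genes, whose calls ended in 3 and 4 of 16 fits without an array (adjusted p up to 0.0591 and 0.0786). Cell division genes did not pass (median -0.05, opposite in sign to the test, adjusted p = 0.875), nor did markers of vascular tissue (0.14, adjusted p = 0.857) and of seed and pollen (0.09, adjusted p = 0.769). The proteasome list (median 0.08, adjusted p = 0.0532) passed in 10 of 20 alternative fits, at the smallest adjusted p, 4.49e-12, under normexp background correction. Photosystem genes passed in 3, NB-LRR genes in 3, in opposite directions, pathogenesis-related genes in 2, cytosolic ribosome genes in 2, again in opposite directions, and WRKY, receptor kinase, diterpenoid, ER and ethylene genes in 1 each. The number of passing lists was 7 without replicate 1 of mock-treated npr1-7, and 4 without its replicate 4 or without replicate 2 of mock-treated wild type.

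The fifth comparison set npr1-7 against wild type after BTH. The Dof-type gene Os02g0252400 and the homeodomain-like gene Os11g0282700 stood at least 67.7-fold and at least 45.9-fold higher in npr1-7, followed by a glycine-rich protein gene (Os07g0511100, at least 29.2-fold), a P450 gene (Os03g0371000, at least 19.3-fold) and a disease resistance family gene (Os11g0605100, at least 12.4-fold, 3 of 4 wild-type arrays well above background). Lower were PR1a (Os07g0129200, -3.62, SE 1.01), the S10 carboxypeptidase gene Os11g0461000 (at least 5.87-fold, 1 of 4 npr1-7 arrays well above background), a pectinesterase gene (Os07g0607400, at least 3.87-fold), a transferase gene (Os10g0380100, -3.06, SE 0.79) and a CYP99A1 gene of the diterpenoid list (Os04g0180400, at least 6.54-fold). Of the PBZ1 genes Os12g0555500, with 3 wild-type arrays, stood at -1.66, SE 0.42 (adjusted p = 0.0214) and Os12g0555300 at -1.41, SE 0.61 (adjusted p = 0.116, not past the threshold). In all 3810 genes differed, 1860 higher and 1950 lower, and 855 at least 2-fold (640 higher, 215 lower). The total was 1463, 2220 and 2373 without replicate 1, 2 or 4 of BTH-treated wild type, 1557 and 1899 without replicate 2 or 3 of BTH-treated npr1-7, 9152 with array weights, 6546 without the 2 arrays together, 6370 without a detection filter, 5818 with probes tested apart and 1051 under normexp background correction, which ended the calls of Os03g0371000, Os07g0607400 and Os04g0180400 (adjusted p = 0.0846, 0.263 and 0.152). Left-out arrays ended the calls of Os07g0129200 (5 of 16 fits, adjusted p up to 0.0739, without replicate 2 of BTH-treated wild type), Os04g0180400 (5 of 16, up to 0.0878, without its replicate 1), Os10g0380100 (2 of 16, up to 0.0682, without the same array) and Os12g0555500 (2 of 16, up to 0.0762, without replicate 2 of BTH-treated wild type).

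Of 40 photosystem and light-harvesting genes 27 were higher in BTH-treated npr1-7 and 0 lower (30 higher adjusted over the list alone), with a median of 1.33 (2.51-fold), or 0.77 with the accidental product names put back. They included PsbX (Os03g0343900, 2.27, SE 0.40), a photosystem I subunit VI gene (Os05g0560000, 2.11, SE 0.40) and oxygen-evolving enhancer proteins 3-2 (Os07g0544800, 1.76, SE 0.34) and 1 (Os01g0501800, 1.61, SE 0.30). The plastid ribosome list had 19 of 46 higher and 5 lower (23 and 7 adjusted over the list alone), the tetrapyrrole list 5 of 16 higher (9 higher and 1 lower) and the Calvin cycle list 4 of 28 higher and 2 lower (7 and 2). Lower in npr1-7 were 16 of 83 pathogenesis-related genes against 3 higher (16 and 3), including chitinase Os10g0416500 (-1.42, SE 0.26) and beta-1,3-glucanase Os01g0941400 (-1.65, SE 0.31). The diterpenoid list had 3 of 6 lower (3), among them Os04g0178300 (at least 7.45-fold, 3 of 4 npr1-7 arrays well above background), the phenylpropanoid list 7 of 29 (10 lower and 1 higher), the ER list 11 of 56 and 1 higher (16 and 1), the cytosolic ribosome list 24 of 143 (28) and the proteasome list 4 of 39 and 1 higher (1 and 1). Preset adjusted p values were 2.71e-15, 0.000547, 0.000599 and 0.0119 for the plastid lists and 0.00635, 0.0353, 0.0207, 0.000463, 5.89e-14 and 0.0187 for the others, and with an estimated correlation the adjusted p was 0.681 for each of the 10. Quantile normalization ended the phenylpropanoid and proteasome calls (adjusted p = 0.170 and 0.251), and scaling to the median the diterpenoid call (adjusted p = 0.0732). The diterpenoid and phenylpropanoid calls ended without replicate 1 of BTH-treated wild type (adjusted p = 0.0536 and 0.126), the diterpenoid call also without its replicate 3 or replicate 4 of BTH-treated npr1-7 (adjusted p = 0.0867 and 0.0902), and the proteasome call without replicate 2 of BTH-treated wild type or replicate 3 of BTH-treated npr1-7 (adjusted p = 0.0604 and 0.0595).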

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

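The test on further probes of the same genes, the measurement of both interaction tests on replicates that had not chosen the genes, with every pair of replicates for the test of scaling, and the choice of the groups' own spread for WRKY45, were made after the results had been seen. The other tests were planned. Among 337 groups of 4 arrays tested for a single distant array, 20 had a gap to the nearest array, as a share of the group's range, above the 95% critical value of Dixon's test, and chance gives about 1 in 20, or 16.9. Of these arrays 5 were replicate 1 of mock-treated wild type. The gap was 0.955 of the range for Os02g0252400, 0.888 for Os06g0602400, 0.970 for Os07g0511100, 0.873 for Os11g0282700 and 0.857 for Os01g0123900 in that array. Of these genes Os02g0252400, Os06g0602400 and Os11g0282700 were named as higher in npr1-7 under mock, and Os07g0511100 after BTH. Os02g0252400 and Os11g0282700 read -4.18 and -4.16 in that array, and 1 of the 4 arrays of its group was well above background for each. The cause was not tested. In mock-treated wild type the gap was also 0.973 for Os01g0108400, 0.832 for Os01g0743500, both in replicate 2, and 0.954 for Os03g0738600 in replicate 3. In mock-treated npr1-7 it was 0.860, 0.950 and 0.899 for Os01g0949700, Os05g0460600 and Os06g0695400 in replicate 1 and 0.887 for Os01g0123900 in replicate 4. In BTH-treated wild type it was 0.846, 0.841 and 0.886 for Os01g0565900, PR1a (Os07g0129200) and Os08g0529100 in replicates 1, 2 and 3, and in BTH-treated npr1-7 0.837, 0.919 and 0.918 for Os01g0823100 in replicate 3 and Os03g0786100 and Os10g0416500 in replicate 4. The median local background gave 0.833 in BTH-treated wild type and 0.917 in mock-treated npr1-7, both for replicate 4. In every group the lowest background was that of replicate 4, at position 4 of its slide. These values were 52 and 42 in mock-treated and BTH-treated wild type, and 51 and 45 in mock-treated and BTH-treated npr1-7.

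The response to BTH differed between the genotypes for 16 features, among them Os01g0144100 (2.32), Os05g0460600 (1.74), Os01g0851000 (1.5), Os10g0513400 (-2.52) and Os10g0514500 (-1.87). A further one, Os06g0642500, had a fitted interaction of 2.63, of unknown size because it was not well above background on any BTH array. It differed for 7 lists by the preset test, with median interactions of 1.04 for photosystems, 0.46 for the Calvin cycle, 0.59 for plastid ribosomes, 0.37 for tetrapyrroles, -0.31 for cytosolic ribosomes, -0.17 for the proteasome and -0.15 for ER folding, and for 0 lists by camera with an estimated correlation (1 at an unadjusted p under 0.05).

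Other splits of the same arrays were counted for every total. In wild type 1 of 35 splits, the real one, gave as many genes changed by BTH (10405, against 4168 at most in another split, which exchanged replicate 3 of both wild-type groups). The real split was also the only one of 35 for npr1-7 after BTH (1559, highest other 25), for the mock comparison (921, highest other 702) and for the comparison after BTH (3810, highest other 495), and 1 of 100 drawn splits for the interaction (16, highest other 1) and for the dependent genes (15, highest other 1). None of these 6 totals was thus reached by another split. The other splits put arrays of groups that differ together, which widens the spread within a group and lowers their counts. They are therefore a limited guide to chance, and they cannot separate group from slide. Chance cannot be excluded for the numbers of lists past the preset test, which 6 of 35 splits reached in wild type (16, highest other 17), 13 of 35 in npr1-7 (12, highest other 17), 35 of 35 under mock (2, highest other 16), 5 of 35 after BTH (10, highest other 13) and 44 of 100 for the interaction (7, highest other 13).

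The target label was the first pattern weighed. A knockdown of WRKY45 requires lower WRKY45 in npr1-7 in both treatments, but after BTH the difference was 0.12, with a 95% interval of -0.31 to 0.54 from the spread of these groups (SE 0.17; the fit over all arrays gives 0.60). With the spread of these groups the values argue against lower WRKY45 transcript after BTH, whereas the wider SE of the fit would not exclude a fall of 0.5, the size set in advance. A knockdown of NPR1 requires lower NPR1 in both treatments, which held after BTH (-1.86, 95% interval -2.53 to -1.19), while the mock difference of -0.36 (95% interval -1.13 to 0.42) leaves it open. Probes that may also read a silencing transcript keep both readings limited to what the arrays detect.

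The smaller response of npr1-7 to BTH was the second pattern. A compressed signal range on the npr1-7 slides is argued against by 10 spike-in probes, whose slopes were 1.001 on wild-type and 0.999 on npr1-7 slides, a difference of -0.14% (SE 0.31). Choosing genes for a large change in wild type can by itself favour a smaller response in npr1-7. Median interactions were -0.62 and 1.04 for induced and repressed genes on the arrays that chose them, and -0.29 and 0.495 for genes chosen on replicates 1 and 2 of wild type and measured against replicates 3 and 4. Over the 6 choices of such a pair they ranged from -0.74 to -0.22 and from 0.50 to 1.49, nearer 0 in each of the 3 that measured on replicate 3, so the smaller values of the first choice cannot be put down to selection alone. A scaling error of whole slides would move both groups of genes in the same direction, so the opposite signs in all 6 choices argue against it (spike-in probes 0.08, SE 0.22), and probe-specific differences are argued against by further probes of such genes, measured in the same way, at -0.25 and 0.506. The test on further probes took the place of a planned one on control probes, of which 25 of 26 with signal had no interaction at an unadjusted p under 0.05. A weaker dose of BTH in the npr1-7 shoots stays open. The shares kept by induced and repressed genes differed by 0.291, where an equal loss was expected, but the planned count of larger responses could tell nothing with 16 called interactions. Slide effects shared by all probes of a gene cannot be told apart from the group, and a dependence on NPR1 stays open as the biological explanation, which 1 line cannot separate from other differences of that line. A share as low as that of the induced genes (0.596) was reached by 7 of 100 splits (lowest other 0.478) and that of the repressed genes (0.305) by 1 of 100 (lowest other 0.337).

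The mock differences were the third pattern, with tissue makeup as the explanation weighed. A different share of growing tissue could lower the markers of expansion and division together, and the medians were -0.185 (adjusted p = 0.191) and -0.05 (adjusted p = 0.875), so that the first lies outside and the second inside the bound of 0.1 set in advance and the question stays open. A different response to shoot excision could lower the dehydration genes, whose median was -0.344 (adjusted p = 0.00285, and 0.511 under normexp background correction at a median of -0.60, and 0.701 with an estimated correlation). The shift set in advance was thus met by the preset test with the main values, but not with an estimated correlation. All shoots were cut, so this response cannot be told apart from other differences between the lines, nor these from the slide. The median did not shrink under normexp background correction, while the call depends on that correction and on the correlation assumed. A biological difference between the lines stays untested.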

How the results depend on the processing

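The alternative without replicate 3 of BTH-treated wild type and replicate 1 of mock-treated npr1-7 together, and the lists with accidental names put back, were added after seeing the data, and the other alternatives were planned. Of the 10 results for the target genes 8 kept their side of the threshold in all 29 alternatives. The number of genes changed by BTH in wild type kept within 1.5 times of 10405 under every alternative except probes tested apart (15777) and the 2-fold threshold (2929). Under normexp background correction 407 genes changed in npr1-7, 111 had an interaction, 2383 differed under mock and 1051 after BTH, 103 were dependent, the repressed share was 0.156 and 8 lists passed under mock. Without a detection filter 6370 genes differed after BTH, and with probes apart 5818. In fits of the compared groups alone 154 differed under mock, and with a trended robust prior 10 had an interaction. With array weights the totals were 7039 in npr1-7, 4008 for the interaction, 4241 under mock, 9152 after BTH and 1594 dependent, and NPR1 passed in npr1-7 (-0.58, adjusted p = 0.0145) and in the interaction (-1.68, adjusted p = 0.00393). With the 2-fold threshold the totals were 554, 301 and 855 for npr1-7, mock and BTH. Without the 2 arrays together they were 2974 in npr1-7, 2357, 3382 under mock, 6546 after BTH and 1298 dependent, with an induced share of 0.433 and an NPR1 interaction of -1.89 (adjusted p = 0.00698). Genes chosen on replicates 1 and 2 and measured on 3 and 4 gave shares of 0.72 and 0.434. With an estimated correlation 0 lists passed camera in each of the 5 contrasts (3, 4, 1, 1 and 0 at an unadjusted p under 0.05 in wild type, npr1-7, the interaction, mock and BTH). The 2-fold threshold, the missing filter and probes tested apart change by construction how many features can be counted. For the other alternatives the cause was not tested.

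Leaving out each array gave ranges of 8293 to 11138 genes in wild type, 628 to 2354 in npr1-7 (without replicates 2 and 1 of its mock group), 0 to 1251 for the interaction and 0 to 786 dependent (without replicate 2 of BTH-treated npr1-7, for example, and replicate 3 of BTH-treated wild type), 287 to 3002 under mock (without replicates 3 and 1 of mock-treated npr1-7) and 1463 to 5400 after BTH (without replicates 1 and 3 of BTH-treated wild type). The shares ranged from 0.497 to 0.685 and from 0.265 to 0.355. NPR1 ranged from 0.91 to 1.28 in wild type, from -0.62 to -0.21 in npr1-7, from -1.71 to -1.31 for the interaction (past the threshold at -1.68 without replicate 3 of BTH-treated wild type), from -0.55 to -0.15 under mock and from -2.04 to -1.68 after BTH. WRKY45 ranged from 4.83 to 5.41, from 5.10 to 6.40, from 0.01 to 1.31, from -1.19 to 0.11 and from 0 to 0.22 in the same order. Lists past the test numbered 14 to 17, 11 to 14, 7 to 12, 2 to 7 and 8 to 13 in wild type, npr1-7, the interaction, mock and BTH.

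The replicate number is also the position of the array on its slide in every group. Deviations from the group means gave little sign that the arrays pair by this number. Of 24 same-number pairs 8 had correlated deviations over 0.1 (r from -0.455 to 0.486), and 6 correlated best with their own number, a hint from the data only. With the replicate block, which is thus also a block for slide position, limma called 0 genes for the interaction (3574 at an unadjusted p under 0.05) and 0 were dependent. The slide block could not be fitted, because each group has its own slide.

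Among values of the named genes and lists that were called with or without an alternative, the direction of the gene's change or of the list's test turned under normexp background correction. It did not turn under quantile normalization, the median, the replicate block or left-out arrays, nor for lists with an estimated correlation or the accidental names, and the other alternatives were not run on these values. The genes that turned were called without that correction and not with it. They were, for BTH in wild type, Os02g0571100 (-0.33), Os12g0555200 (-0.30), Os04g0179200 (-0.006), Os09g0533200 (-0.91), Os04g0178400 (-0.53), Os02g0627900 (-0.29), Os02g0751300 (-0.024) and Os04g0546500 (-0.34), and under mock Os06g0602400 (-0.68), Os02g0186800 (-1.06), Os09g0457100 (-0.039), Os03g0179900 (0), Os11g0673600 (-0.81), Os11g0265900 (-0.38), Os11g0161700 (-0.13) and Os06g0163900 (-0.88). A further 97 values of named genes lost their call without turning. The lists whose test turned were called with it but not with the main values. They were NB-LRR genes, with medians of -0.77 in wild type, 0.69 in the interaction and -0.71 under mock, and, under mock, cytosolic ribosomes (0.066) and ER folding (-0.021), whose median stayed negative while its test turned. A further 12 list values gained a call with it without turning. The diterpenoid list in wild type lost its call while its median went from 2.1 to -0.26 (adjusted p = 0.740). The cause was not tested. Over the 651 named gene values, 338 of them called, 7, 8, 97 and 30 calls ended under quantile normalization, the median, normexp and the replicate block, and 562 of 5408 in fits without an array. Of 47 called list values 4, 1, 9 and 1 ended, in the same order, and 0 with the accidental names put back. Between 69.9 and 75.2% of spots were well above background, so changes of genes near background are limited by the signal, and normexp moved the median of all genes under mock by -0.24.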

Other observations

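The test of the WRKY45 hypothesis, with its bounds, was chosen after the values had been seen. Of 80 tested microRNA probes 29 changed with BTH in wild type, 3 in npr1-7, 5 differed under mock and 13 after BTH. Both microRNA probes with a called interaction carry the name osa-miR398b and were picked out after their values were seen. They are labelled as 5′ and 3′ sequences under that same name, so they are not independent observations. Whether such probes read the mature microRNA or a longer transcript is not known from the sources used here. They changed by -2.18 and -2.49 in wild type and by 0.18 and 0.12 in npr1-7, interactions of 2.36 and 2.61 (limma adjusted p = 0.0335 each). These calls ended in the fits without any called interaction. Those were the fits with the replicate number as a block, without replicate 2 of BTH-treated npr1-7, and without replicate 2 or 3 of mock-treated npr1-7. Without replicate 3 of BTH-treated npr1-7 only 1 feature was called in all, so the probes cannot both have kept their calls there. Their calls in the other fits were not followed. Among lists that did not pass the preset test after BTH, the nearest were shikimate genes, with 7 of 29 lower and 1 higher in npr1-7 (adjusted p = 0.0541, past the test in 9 of 20 alternative fits), and heat shock genes, with 6 of 40 lower and 1 higher (adjusted p = 0.0541, past in 7). Vascular markers had a median of 1.06 with 0 of 9 called (adjusted p = 0.0628), and passed when scaled to the median (adjusted p = 0.0301) or without replicate 3 of BTH-treated wild type, replicate 3 of BTH-treated npr1-7 or replicate 2 of mock-treated npr1-7 (adjusted p = 0.0110, 0.0300 and 0.0487).

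WRKY45 spread widely among the mock-treated npr1-7 arrays, at -3.85, -1.5, -1.34 and 0.03 in replicates 1 to 4. A hypothesis is that these shoots differed in how far the BTH-responsive genes were already on, in which case induced and repressed genes deviate in opposite directions. The median deviations of the wild-type induced genes from the group mean were -0.39, -0.04, 0.07 and 0.33, a difference of 0.72 between the arrays with the highest and the lowest WRKY45. The repressed genes deviated by 0.00, 0.12, -0.01 and -0.07. In the arrays with the lowest and the highest WRKY45 the induced genes deviated in its direction. The repressed genes deviated by 0.00 and -0.07 there, short of the bound of 0.2. Little of the opposite shift was thus seen in these npr1-7 arrays, and the hypothesis stays open. NPR1 rose in the same order over these mock-treated npr1-7 arrays, at -2.32, -1.84, -1.47 and -1.11. In mock-treated wild type, at -1.46, -1.03, -1.32 and -1.52, it did not follow WRKY45. In the 4 mock-treated wild-type arrays the induced genes deviated by 0.12, -0.17, 0.24 and -0.22 at WRKY45 of -0.64, -1.61, -0.10 and -1.83. The repressed genes deviated by 0.18, 0.03, -0.21 and 0.04 there. Replicate 3, with the highest WRKY45 of these arrays, thus showed the opposite shift past the bound of 0.2. In replicate 4, with the lowest, the repressed genes fell short of it.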
